A study of Mus musculus with 8 samples.

How the data were processed

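The deposited table holds 1 value per probe set and array, made with RMA (robust multi-array averaging) per the submitters' processing notes. The values were taken as the log2 values of the authors, since log2 is the convention of RMA, although the table itself does not state the base. They are printed to 2 decimals. They were used as deposited, with no further normalisation, no filter on dim probe sets and no pseudocount.

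The gene table paired 30294 of the 40161 probe sets with 1 gene symbol, and these were tested. Of the remaining 9867 probe sets, 2145 carried several symbols and 7722 carried none, and no probe set was marked as a control. The tested probe sets stand for 29915 genes. Through Entrez IDs, 22546 were matched to the RefSeq gene table of mouse assembly GRCm38.p6, which updated 827 symbols. That table served only for names and for the order of neighbouring genes, because the genome build of the array is not named.

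All comparisons come from 1 model with the mean of each of the 4 groups, fitted with limma 3.58.1 (lmFit and eBayes) and statmod 1.5.0 in R 4.3.3. The 4 groups shared 1 estimate of the spread of each probe set, with 4 residual and 2.59 prior degrees of freedom and a median residual SD of 0.182 log2. Tests were two-sided. P values were adjusted by the Benjamini-Hochberg method over the 30294 probe sets within each comparison, and an adjusted p under 0.05 counted as passed. Standard errors (SE) and 95% confidence intervals are those of the same limma fit, and the number of arrays limits their precision.

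Before the data were examined, 7 comparisons and 28 gene lists were fixed, with 604 genes of which 550 were measured. The lists cover p53 target genes, DNA double-strand break repair, Bcl2 family and caspases, G2/M and mitosis, G1/S and DNA replication, LT-HSC identity, quiescence regulators, HSC ageing and myeloid bias, type I interferon response, interferon-gamma response and MHC class I, NF-kB and inflammatory cytokines, immediate early and stress genes, NRF2 and antioxidant defence, oxidative phosphorylation, glycolysis and hypoxia, unfolded protein response, ribosome biogenesis and Myc, TGF-beta and BMP response, niche receptors and adhesion, and iron and haem handling. The other 8 lists hold markers of cells that the sorting gate could hold besides LT-HSC: megakaryocyte lineage, erythroid lineage, neutrophil and granulocyte-monocyte progenitor, monocyte and macrophage, lymphoid progenitor, mature T, NK and B cell, mast cell, basophil and eosinophil, and endothelial and stromal.

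Each list was tested with camera of limma at its preset inter-gene correlation of 0.01, on the probe set of each gene with the highest mean over the arrays, and adjusted over the 28 lists within a comparison. A list counted as called at an adjusted p under 0.05. Members were also adjusted over their list alone within 1 comparison. That p is not adjusted over the 28 lists or the 7 comparisons, so members that passed it can include chance findings. Camera compares a list with all other genes, whose median shift lay between -0.05 and 0.075 log2 in the 7 comparisons. Camera with an estimated correlation and fry were run beside it. With the estimated correlation no list was called in any of the 7 comparisons, with fry 1 list was called for irradiation in WT, 1 in CD169-DTR and 2 for the average, and 0 in the other 4 comparisons. The median, the mean and the test had the same sign for every called list. List means are given with the SD over members.

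Named genes were chosen by rule. The rule takes the 10 probe sets with the largest rise and the 10 with the largest fall among those that passed, then those with the smallest unadjusted p, a fold change of at least 1.5 and groups that do not overlap. It adds up to 4 members of each list with the smallest p, and always Siglec1, Cdkn1a, Mdm2, Ccng1, Phlda3, Kit, Slamf1, Cd48, Flt3 and Mki67. Predicted genes, olfactory receptors and genes with no known role were passed over, and the text gives a choice among the genes so found. Bax and Ly6a, which the rule also names, are not analysed here because no tested probe set carried their symbol.

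The alternatives tried were an intensity trend with robust hyperparameters, a filter that kept probe sets above the 40th percentile of the mean, all probe sets with or without a symbol, cyclic loess, median centring, array weights, the replicate number as a block, only the groups compared, an unadjusted p under 0.05 with a fold change of at least 1.5, and each of the 8 arrays left out in turn. Leaving out both 2 Gy arrays farthest from the others was added after seeing the data. Where an array was left out, its partner was assumed to vary like the arrays of the other groups. A probe set that stands apart in that partner alone can then pass, so a higher count is not read as more changed genes.

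In a self-test on simulated values with the residual spread of these arrays, 100 of the 30294 probe sets were changed 2-fold and 100 others 8-fold in the same run. The WT irradiation comparison recovered 23 of the former and 99 of the latter, with 6 false calls among the unchanged probe sets. The averaged comparison recovered 67 and 99 with 4 false calls, and the interaction 0 and 87 with 5 false calls. So many changed genes loosen the Benjamini-Hochberg threshold, whereas 0 to 3 probe sets passed in the real comparisons. Recovery in the real arrays can therefore be lower than these shares. For example, Cdkn1a was 12.7-fold higher after irradiation in CD169-DTR and had an adjusted p of 0.0622 in limma. In 20 runs with the p53 list shifted by 0.5 log2, camera called it in 20 runs and in 14 with an estimated correlation, and 1 of 500 unshifted lists was called. All simulated genes were drawn independently of each other. The self-test therefore does not show how often lists of correlated genes are called falsely in the real arrays.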

Results

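Gene expression was measured on 8 Affymetrix arrays of RNA from mouse long-term haematopoietic stem cells (LT-HSC), sorted as Lin-, cKit+, Sca+, Flk2-, CD48- and CD150+ cells. The cells came from wild-type (WT) mice and from CD169-DTR mice (genotype CD169DTR/+ in the sample titles), which are heterozygous for the diphtheria toxin receptor under the control of the gene of CD169 (Siglec1). All mice received the toxin, which depletes CD169+ macrophages in the CD169-DTR mice. They were then given total body irradiation of 2 Gy or left non-irradiated, and LT-HSC were isolated at day 5. The 4 groups, WT non-irradiated, WT 2 Gy, CD169-DTR non-irradiated and CD169-DTR 2 Gy, held 2 arrays each, from distinct experiments per the submitters' design text.

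The median log2 value per array lay between 4.76 and 4.93. Replicates of a group correlated across probe sets with a Pearson r of 0.991 to 0.994. For 4 of the 8 arrays the r with an array of another group (0.9921 to 0.9937) was higher than that with their partner. On the first principal component, with 21.7% of the variance, CD169-DTR 2 Gy replicate 2 (40.3) and WT 2 Gy replicate 1 (29.5) lay farthest from the other arrays, and on the second (19.7%) they lay at opposite ends (36.8 and -45.3). Siglec1, the gene of CD169, had a mean of 3.90 ± 0.04 log2 in WT non-irradiated LT-HSC (SD, n = 2). Kit, the receptor for stem cell factor on which the gate relied, had a mean of 14.91 ± 0.03.

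The comparison of WT 2 Gy with WT non-irradiated LT-HSC asks what differed 5 days after irradiation in mice with CD169+ macrophages. Cdkn1a, an inhibitor of cyclin-dependent kinases and a p53 target, rose from 8.13 ± 0.38 to 13.24 ± 0.25 log2 (SD, n = 2 each). This is a 34.5-fold rise with a 95% interval of 23.3 to 51.3 and an adjusted p of 0.0073 in limma. Mmp2, a matrix metalloproteinase, rose 4.30-fold (3.40 to 5.45, adjusted p = 0.0397). Cxcr4, the receptor for the niche chemokine Cxcl12, fell by 1.66 ± 0.12 log2 (SE), which is 3.16-fold (adjusted p = 0.0397). In each of these 3 genes both irradiated arrays lay on 1 side of both controls.

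These 3 were the probe sets that passed in limma among 30294, 2 higher and 1 lower, while 2365 had an unadjusted p under 0.05 where chance gives 1514.7 on average. Since genes are not independent, a count due to chance can lie far from that average. The number alone therefore shows neither an excess nor a lack of changed genes, here and in the other comparisons. The Cdkn1a call was lost without WT non-irradiated replicate 1 (4.85 log2, adjusted p = 0.075). The Mmp2 call remained without WT 2 Gy replicate 2, and its log2 rise was 1.99 to 2.23 over the 8 arrays left out. The call was lost without WT non-irradiated replicate 1 (0.242) or 2 (0.479), WT 2 Gy replicate 1 (0.0847), CD169-DTR non-irradiated replicate 1 or 2 (0.123 each) and CD169-DTR 2 Gy replicate 1 or 2 (0.135 each). The Cxcr4 call was lost without each of the 8 arrays, with a log2 difference between -1.70 and -1.62. The adjusted p was 0.434 and 0.524 without WT non-irradiated replicates 1 and 2, 0.14 and 0.075 without WT 2 Gy replicates 1 and 2, 0.123 without either CD169-DTR non-irradiated array and 0.135 without either CD169-DTR 2 Gy array. With all 8 arrays, the Mmp2 call was also lost with the intensity trend (0.0762), cyclic loess (0.0524) and the replicate block (0.0636). The Cxcr4 call was lost with the dim filter (0.0519), cyclic loess (0.0957) and the replicate block (0.194). The count was 0 without WT non-irradiated replicate 1, 1 without WT non-irradiated replicate 2, 7 without WT 2 Gy replicate 1 and 16 without WT 2 Gy replicate 2. Without both 2 Gy arrays farthest from the others, a setting chosen after seeing the data, 2 probe sets passed, both immunoglobulin genes (Ighg2b and Ighv1-39) and none of the 3. The count was 1 (Cdkn1a) with cyclic loess or the replicate block and 0 with only the compared groups in the fit.

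**Figure D1:**
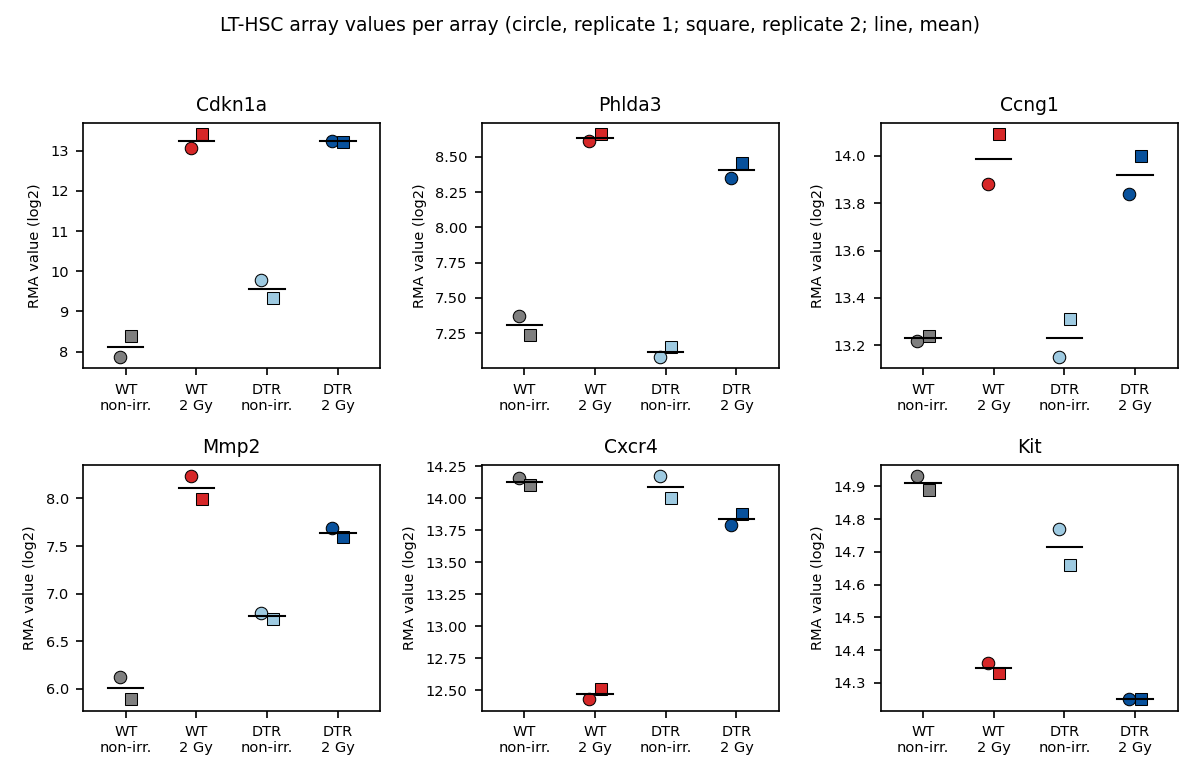
RMA values (log2, y axis) of Cdkn1a, Phlda3, Ccng1, Mmp2, Cxcr4 and Kit in each of the 4 groups (x axis), with circles for replicate 1, squares for replicate 2 and lines for the means. Cdkn1a lies at 13.06 or above in the 4 irradiated arrays and at 9.79 or below in the others, and Cxcr4 lies at 12.51 or below in the WT 2 Gy arrays and at 13.79 or above in the other 6.

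Among the lists, p53 target genes rose after irradiation in WT, with 22 of 25 measured members higher and a mean of 0.618 ± 1.08 log2 (adjusted p = 9.95e-05). With an estimated correlation the adjusted p was 0.112. Cdkn1a passed over all genes, and Cdkn1a, Phlda3, Ccng1 and Eda2r passed when adjusted over the list alone. Phlda3, an inhibitor of Akt, had a log2 difference of 1.33 ± 0.12 (SE) and an adjusted p of 0.101 over all genes, Ccng1 (cyclin G1) 0.755 ± 0.13 and Eda2r, a death receptor, 2.24 ± 0.55. Mdm2, the ubiquitin ligase of p53, had 0.26 ± 0.23 and did not pass.

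Genes of niche receptors and adhesion fell in WT, with 19 of 24 members lower and a mean of -0.282 ± 0.561 (adjusted p = 2.29e-06, and adjusted p = 0.112 with an estimated correlation). Cxcr4 passed over all genes. Cxcr4, Kit (-0.565), Robo4 (-1.06), the receptor subunit Il6st (-0.935) and Notch2 (-0.915) passed when adjusted over the list alone. LT-HSC identity genes fell, 18 of 28 lower with a mean of -0.193 ± 0.544 (adjusted p = 9.95e-05, and adjusted p = 0.329 with an estimated correlation). None passed over all genes, and Sult1a1 (-1.44), Robo4 and Hlf (-0.64), a transcription factor of stem cells, passed when adjusted over the list alone. Immediate early and stress genes fell, 13 of 20 lower with a mean of -0.354 ± 0.644 (adjusted p = 0.000142, and adjusted p = 0.251 with an estimated correlation). Fosb (-2.22), a subunit of AP-1, and Dusp1 (-1.66), a phosphatase of MAP kinases, passed when adjusted over the list alone and none over all genes. NRF2 and antioxidant genes fell by a smaller mean of -0.153 ± 0.333, with 12 of 19 lower (adjusted p = 0.00467, and adjusted p = 0.251 with an estimated correlation), and Txnrd1 (thioredoxin reductase, -0.77) passed when adjusted over the list alone. These 4 lists and the p53 list kept their calls without any 1 of the 8 arrays. The LT-HSC identity list had -0.335 without WT 2 Gy replicate 1 and -0.0504 without its replicate 2, and the immediate early list -0.225 without WT non-irradiated replicate 1.

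Markers of other cells moved with these groups in WT. Neutrophil and granulocyte-monocyte progenitor genes rose, 14 of 18 higher with a mean of 1.26 ± 1.42 (adjusted p = 0.000455, and adjusted p = 0.251 with an estimated correlation), and the call remained without any 1 of the 8 arrays. S100a8, a calcium-binding protein of neutrophils (4.22), Elane (neutrophil elastase, 2.01), Ctsg (cathepsin G, 1.8) and Ms4a3 (2.52) passed when adjusted over the list alone and none over all genes. For S100a8 the WT non-irradiated replicates differed, at 6.74 and 10.38. For Elane, Ctsg and Ms4a3 the WT 2 Gy replicates differed, at 12.8, 9.81 and 9.77 in replicate 1 and 14.57, 11.29 and 11.73 in replicate 2. The rise of these 3 genes was thus larger in WT 2 Gy replicate 2. Megakaryocyte genes stood 0.911 log2 above their mean over the arrays in WT 2 Gy replicate 1 and -0.199 from it in replicate 2, and the list was not called (adjusted p = 0.213). Cd48, whose protein the gate excludes, had 1.44 ± 0.50 (adjusted p = 0.582), and Slamf1 (CD150) had 0.73 ± 0.45 (adjusted p = 0.696).

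A further 7 lists were called in WT and lost the call without at least 1 array; with an estimated correlation their adjusted p was 0.243 to 0.452. HSC ageing and myeloid bias genes fell (-0.134 ± 0.661, adjusted p = 0.00271), which was lost without WT non-irradiated replicate 2 (0.000714 log2, 0.0903) or WT 2 Gy replicate 2 (0.0425 log2, 0.216), so no fall was left without either. In that list Selp (P-selectin, 1.68) and Cavin2 (1.02) were higher and passed when adjusted over the list alone. Type I interferon genes (-0.102 ± 0.276, adjusted p = 0.00458) and interferon-gamma genes (-0.114 ± 0.262, adjusted p = 0.00271) fell only with WT 2 Gy replicate 2, without which the means were 0.0155 and -0.0114 (adjusted p of 0.261 and 0.181). Glycolysis genes (-0.114 ± 0.214, adjusted p = 0.00475) lost the call without WT non-irradiated replicate 2 (0.0572). Unfolded protein response genes (-0.134 ± 0.344, adjusted p = 0.0119), among them Xbp1 (-0.98), lost it without WT 2 Gy replicate 1 (0.123). Quiescence regulators (-0.114 ± 0.346, adjusted p = 0.0129) lost it without WT 2 Gy replicate 1 (0.123) and without WT non-irradiated replicate 1 (0.0604). Monocyte and macrophage genes rose (0.246 ± 0.48, adjusted p = 0.0451), which was lost without WT non-irradiated replicate 1 (0.0604) or 2 (0.0845), WT 2 Gy replicate 1 (0.123) or either CD169-DTR 2 Gy array (0.0628). Where the call remained, the mean was larger without WT 2 Gy replicate 1 for the ageing (-0.31), type I interferon (-0.219) and interferon-gamma (-0.216) lists and without WT 2 Gy replicate 2 for quiescence (-0.182). Without WT non-irradiated replicate 1 it was -0.268 for ageing and -0.0759 for interferon-gamma. In all, 13 of 28 lists were called in WT, 3 higher and 10 lower, and 11 without both far 2 Gy arrays. There the glycolysis (0.0777), unfolded protein response (0.123), quiescence (0.158) and monocyte (0.163) lists were lost and 2 others gained. With the dim filter the 7 further lists were all lost (0.0782 to 0.149) and the other 6 remained. With cyclic loess the quiescence, type I interferon, glycolysis, unfolded protein response and monocyte lists were lost (0.0559 to 0.151) and 3 others gained.

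The comparison of CD169-DTR 2 Gy with CD169-DTR non-irradiated LT-HSC asks the same question in mice depleted of CD169+ macrophages. Cdkn1a was 12.7-fold higher (95% interval 8.58 to 18.89) at 13.24 ± 0.01 against 9.57 ± 0.32 log2 (SD, n = 2), with an adjusted p of 0.0622 in limma. Phlda3 was 2.45-fold higher (2.02 to 2.96, adjusted p = 0.163), and E2f7, a repressor of the cell cycle, 2.53-fold (adjusted p = 0.244). Mir148a, a microRNA gene, stood at 6.06 ± 0.48 in the non-irradiated group and at 3.0 ± 0.11 after 2 Gy (SD, n = 2, adjusted p = 0.087). The latter lies below the 25th percentile of every array (3.85 to 4.04), so no size of the difference is given. Mmp2 had 0.875 ± 0.14 (adjusted p = 0.466) and Cxcr4 had -0.25 ± 0.12 (adjusted p = 0.789).

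With limma, 0 probe sets passed in CD169-DTR and 2050 had an unadjusted p under 0.05. Cdkn1a passed with an intensity trend (adjusted p = 0.024), with the dim filter (0.0418) and with cyclic loess (0.0451), within a range of 0.024 to 0.232 over its alternatives. The count was 1 without either WT non-irradiated array, 5 without CD169-DTR non-irradiated replicate 1, 4 without its replicate 2 and 4 without CD169-DTR 2 Gy replicate 2. It was 4, all immunoglobulin genes such as Ighg2b, without both far 2 Gy arrays, 2 with the trend, cyclic loess or all probe sets, and 1 with only the compared groups.

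The p53 targets rose in CD169-DTR, with 23 of 25 higher and a mean of 0.578 ± 0.788 (adjusted p = 6.71e-07, and adjusted p = 0.104 with an estimated correlation). None passed over all genes, and Cdkn1a, Phlda3, Ccng1 (0.69), Ephx1 (epoxide hydrolase, 1.31) and Zmat3 (0.58) passed when adjusted over the list alone. Type I interferon genes fell, 28 of 30 lower with a mean of -0.398 ± 0.429 (adjusted p = 1.07e-09, and adjusted p = 0.238 with an estimated correlation). Of these Rtp4 (-1.55), Oasl1 (-0.955), Oasl2 (-0.69), Ddx58 (the RNA sensor RIG-I, -0.77) and Cmpk2 (-0.82) passed when adjusted over the list alone. Both lists kept their calls without any 1 of the 8 arrays.

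A further 13 lists were called in CD169-DTR, and their adjusted p was 0.238 to 0.662 with an estimated correlation. Among the 4 higher lists were G2/M and mitosis (0.292 ± 0.22, adjusted p = 0.00056) and G1/S and DNA replication (0.207 ± 0.231, adjusted p = 0.00935). The others were DNA double-strand break repair (0.245 ± 0.349, adjusted p = 0.0159) and mast cell, basophil and eosinophil (1.07 ± 1.38, adjusted p = 0.00594). Among the 9 lower lists were erythroid lineage (-0.92 ± 1.14, adjusted p = 2.67e-05), LT-HSC identity (-0.209 ± 0.383, adjusted p = 0.000386), interferon-gamma and MHC class I (-0.227 ± 0.461, adjusted p = 0.00244), and iron and haem handling (-0.205 ± 0.329, adjusted p = 0.00605). Also lower were niche receptors (-0.16 ± 0.494, adjusted p = 0.00678), quiescence regulators (-0.175 ± 0.208, adjusted p = 0.0126), unfolded protein response (-0.142 ± 0.307, adjusted p = 0.0145), NF-kB and inflammatory cytokines (-0.13 ± 0.349, adjusted p = 0.0159) and immediate early genes (-0.31 ± 0.795, adjusted p = 0.0227). Among niche receptors, Kit (-0.465), Flt3 (-1.63, whose protein Flk2 the gate excludes) and the integrin Itgal (1.09) passed when adjusted over the list alone. Others were Fosb (-2.67), Fos (-1.83) and Nr4a2 (0.885) among immediate early genes, and Gbp8 (-1.77), a guanylate-binding protein, in the interferon-gamma list. Pdgfrb (-2.33), a receptor of stromal cells, passed when adjusted over the endothelial and stromal list alone, which was not called.

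Each of these 13 calls was lost without at least 1 array. Without CD169-DTR non-irradiated replicate 2, in which erythroid genes stood 1.09 log2 above their mean over the arrays, the erythroid list had -0.222 (adjusted p = 0.59) and the iron list -0.0284 (0.545). Without it the unfolded protein response (0.675), immediate early (0.128) and niche (0.0669) lists were lost. Without CD169-DTR non-irradiated replicate 1, the G1/S list had 0.0356 (0.983), and the G2/M (0.11), repair (0.75), quiescence (0.268), NF-kB (0.142) and immediate early (0.0654) lists were lost. Without CD169-DTR 2 Gy replicate 1, the mast cell (0.14), repair (0.147), iron (0.0864), quiescence, NF-kB and immediate early (0.0675 each) lists were lost. Without CD169-DTR 2 Gy replicate 2, the G1/S (0.311), unfolded protein response (0.358), interferon-gamma (0.0558), LT-HSC identity (0.0539), quiescence, NF-kB and immediate early (0.0522 each) lists were lost. Where the call remained, the mean was larger without CD169-DTR non-irradiated replicate 1 for the erythroid (-1.62), iron (-0.382) and unfolded protein response (-0.239) lists and smaller for LT-HSC identity (-0.109). It was larger without its replicate 2 for G1/S (0.379) and quiescence (-0.307), and without CD169-DTR 2 Gy replicate 1 for G1/S (0.316), LT-HSC identity (-0.324) and the unfolded protein response (-0.239). The number of called lists, 15, was 9 without either CD169-DTR 2 Gy array and 12 without both far 2 Gy arrays, where 8 remained, 7 were lost and 4 others were gained. Those lost were G1/S (0.21), LT-HSC identity (0.0541), interferon-gamma (0.0876), NF-kB (0.0578), immediate early (0.102), unfolded protein response (0.34) and niche (0.0517). With the dim filter the NF-kB (0.0513) and unfolded protein response (0.0841) lists were lost. Neutrophil and progenitor genes had -0.301 ± 0.674 and were not called (adjusted p = 0.0805). Cd48 had 1.44 ± 0.50, and Mdm2 (0.08) and Slamf1 (0.13) changed sign without CD169-DTR non-irradiated replicate 2 (-0.23 and -0.415) or CD169-DTR 2 Gy replicate 1 (-0.09 and -0.225).

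**Figure D2:**
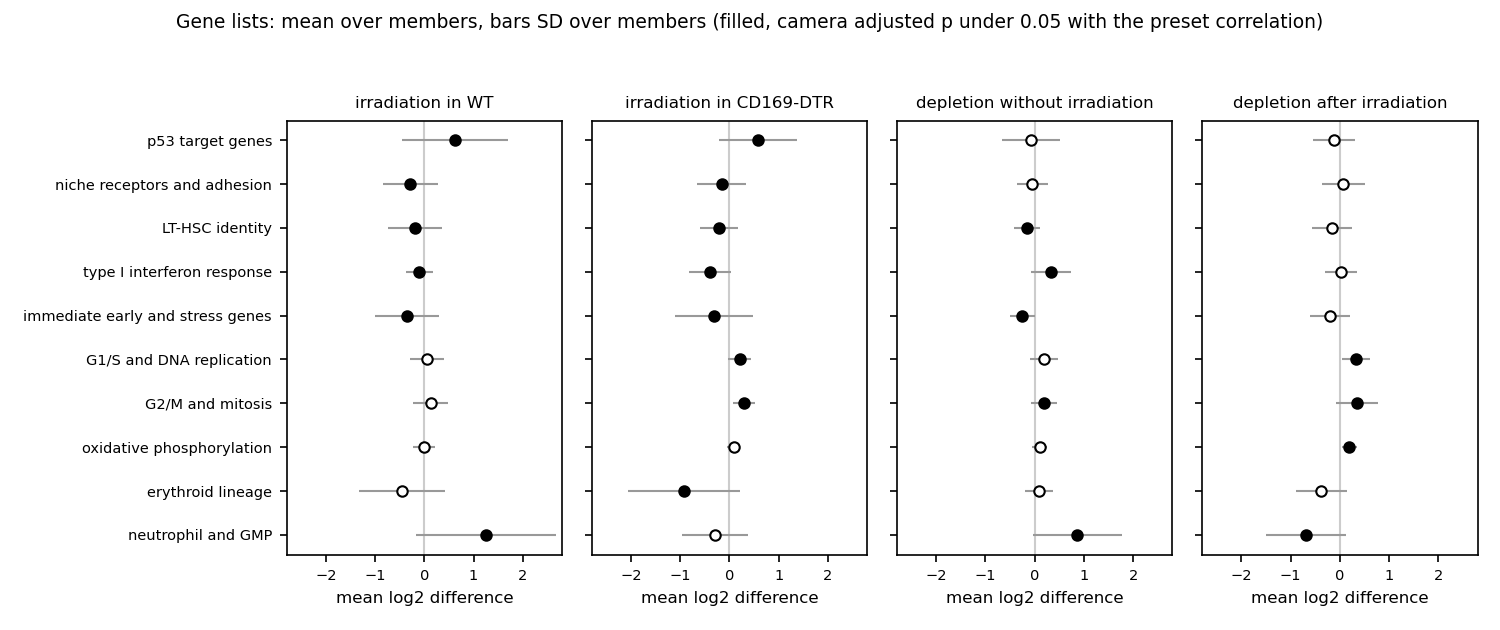
Mean log2 difference over the members (x axis) of 10 gene lists (y axis) in the 4 comparisons between pairs of groups, with bars for the SD over members and filled points for an adjusted p under 0.05 in camera with its preset correlation. The p53 target genes lie at 0.618 and 0.578 after irradiation in WT and CD169-DTR, and the neutrophil and granulocyte-monocyte progenitor (GMP) genes at 1.26 and -0.301.

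The average of the irradiation effects gives both genotypes the same weight. A difference that is large in 1 genotype alone can pass in it, so a call does not show a change common to both. Cdkn1a rose 21.0-fold (95% interval 15.9 to 27.7, adjusted p = 0.00205 in limma, n = 4 against 4), Phlda3 rose 2.48-fold (2.17 to 2.84, adjusted p = 0.0244) and Mmp2 rose 2.81-fold (2.38 to 3.32, adjusted p = 0.0264), each higher in all 4 irradiated arrays than in the 4 others. Genes with the smallest p below these did not pass, with Cxcr4 at -0.955 ± 0.08 log2 (SE, adjusted p = 0.11). Ccng1 (0.722), E2f7 (0.842), Gas6 (a ligand of TAM receptors, 0.892), Sqle (squalene epoxidase of sterol synthesis, -0.822) and Fosb (-2.44) had an adjusted p of 0.209. Cd48 had 1.44 ± 0.35, Slamf1 0.43 ± 0.32 and Mki67, a marker of cycling cells, 0.412 ± 0.20, and none of these passed.

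These 3 probe sets were those that passed in the average, against 2795 with an unadjusted p under 0.05, and the Cdkn1a call remained under all alternatives that kept at least 7 arrays. The Phlda3 and Mmp2 calls remained without WT 2 Gy replicate 2 and were lost with the intensity trend (0.06). Both were lost without WT non-irradiated replicate 1 (0.128) or 2 (0.146) and without WT 2 Gy replicate 1 (0.0798). Both were also lost without CD169-DTR non-irradiated replicate 1 (0.0958 for Phlda3, 0.109 for Mmp2) or 2 (0.132, 0.157) and without CD169-DTR 2 Gy replicate 1 (0.0634, 0.103) or 2 (0.0682, 0.086). The log2 rises were 1.28 to 1.34 for Phlda3 and 1.43 to 1.55 for Mmp2. Phlda3 was also lost with the replicate block (0.0768). The count was 1 with the trend, 1 without CD169-DTR non-irradiated replicate 2, 6 without CD169-DTR 2 Gy replicate 2 and 12 without WT 2 Gy replicate 2. Without both far 2 Gy arrays it was 3, all immunoglobulin genes such as Ighg2b and none of the 3 above.

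Across the 30294 probe sets the irradiation effects of the genotypes had a Pearson r of 0.167 and a Spearman rho of 0.142, and 57.5% had the same sign. Genes are not independent replicates, so no p is given. The r was 0.1 without CD169-DTR non-irradiated replicate 2. Of the 579 probe sets with an unadjusted p under 0.01 in WT and the 479 in CD169-DTR, 70 were shared, 55 in the same direction. Both p values use the same estimate of the spread of a probe set, so they are not independent.

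Of the lists, p53 targets rose in the average, 23 of 25 higher with a mean of 0.598 ± 0.903 (adjusted p = 1.68e-07, and adjusted p = 0.0593 with an estimated correlation). Cdkn1a and Phlda3 passed over all genes. Adjusted over the list alone, Ccng1, Zmat3 (0.512), Eda2r (1.68), Plk2 (0.888) and Ephx1 (0.662) passed as higher beside them and Plk3 (-0.562) as lower. Niche receptors fell, 19 of 24 lower with a mean of -0.221 ± 0.441 (adjusted p = 1.04e-06, and adjusted p = 0.0593 with an estimated correlation). Cxcr4, Kit (-0.515), Flt3 (-1.32), Notch2 (-0.747), Robo4 (-0.697), Selplg (the ligand of P-selectin, -0.522), Fgfr1 (-0.437) and, as higher, Itgal (0.847) passed when adjusted over the list alone and none over all genes. Of these, the gate selects for the protein of Kit and excludes that of Flt3. Type I interferon genes fell, 25 of 30 lower with a mean of -0.25 ± 0.297 (adjusted p = 2.42e-08, and adjusted p = 0.219 with an estimated correlation). Most of that fall came from CD169-DTR. Its non-irradiated arrays stood 0.336 and 0.241 log2 above the mean over the arrays, while the WT non-irradiated arrays stood at -0.0423 and -0.0353. LT-HSC identity genes fell, 18 of 28 lower with a mean of -0.201 ± 0.396 (adjusted p = 1.04e-06, and adjusted p = 0.219 with an estimated correlation). Of these 6 passed as lower when adjusted over the list alone, among them Hlf (-0.548), Sult1a1 (-1.25) and Txnip (-0.518), and 1 as higher, Ctnnal1 (0.573). Immediate early genes fell, 13 of 20 lower with a mean of -0.332 ± 0.688 (adjusted p = 0.000204, and adjusted p = 0.219 with an estimated correlation), with Fosb, Fos (-1.36), Dusp1 (-1.17), Jun (-0.83) and Egr1 (-0.47) as lower and Nr4a2 (0.52) as higher past the threshold when adjusted over the list alone. Interferon-gamma genes (-0.17 ± 0.26, adjusted p = 2.87e-05) and quiescence regulators (-0.145 ± 0.245, adjusted p = 0.00173) fell as well, at adjusted p = 0.219 with an estimated correlation for both. These 7 lists kept their calls without any 1 of the 8 arrays and without both far 2 Gy arrays. LT-HSC identity had -0.13 without WT 2 Gy replicate 2 and quiescence -0.079 without CD169-DTR non-irradiated replicate 1.

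A further 9 lists were called in the average, and their adjusted p was 0.219 to 0.555 with an estimated correlation. Erythroid lineage (-0.689 ± 0.989, adjusted p = 5.94e-05), unfolded protein response (-0.138 ± 0.255, adjusted p = 0.00165) and iron and haem handling (-0.12 ± 0.283, adjusted p = 0.00165) fell, all lost without CD169-DTR non-irradiated replicate 2 (0.0676). NF-kB genes fell (-0.107 ± 0.219, adjusted p = 0.0109), which was lost without CD169-DTR non-irradiated replicate 1 (0.0641). G2/M genes rose (0.212 ± 0.232, adjusted p = 0.0109), which was lost without WT 2 Gy replicate 2 (0.0535 log2, 0.822), CD169-DTR non-irradiated replicate 1 (0.137) or CD169-DTR 2 Gy replicate 1 (0.0628). HSC ageing genes fell (-0.0933 ± 0.455, adjusted p = 0.0109), lost without WT non-irradiated replicate 2 (0.124), WT 2 Gy replicate 2 (-0.00527 log2, 0.201), CD169-DTR non-irradiated replicate 1 (0.0737) or CD169-DTR 2 Gy replicate 2 (-0.00223 log2, 0.208). NRF2 genes (-0.0791 ± 0.194, adjusted p = 0.0304), ribosome biogenesis and Myc genes (-0.104 ± 0.227, adjusted p = 0.0451) and glycolysis genes (-0.039 ± 0.207, adjusted p = 0.0489) fell. These last 3 were lost without WT non-irradiated replicate 2 (0.0677, 0.0997 and 0.159), WT 2 Gy replicate 1 (0.0665, 0.445 and 0.126) or CD169-DTR non-irradiated replicate 2 (0.244, 0.942 and 0.219), where the ribosome list had 0.0067 log2. The NRF2 list was also lost without CD169-DTR 2 Gy replicate 2 (0.108), and the ribosome (0.3) and glycolysis (0.254) lists also without CD169-DTR 2 Gy replicate 1. Where the call remained, the mean without WT 2 Gy replicate 1 was 0.37 for G2/M, -0.181 for ageing and -0.048 for iron, and without WT 2 Gy replicate 2 it was -0.192 for iron and -0.164 for ribosome genes. Without CD169-DTR non-irradiated replicate 1 it was -1.04 for erythroid, -0.208 for iron and -0.215 for ribosome genes. For ageing it was -0.16 without WT non-irradiated replicate 1 and -0.184 without CD169-DTR 2 Gy replicate 1, and for the unfolded protein response -0.0891 without CD169-DTR 2 Gy replicate 2. The count was 16 of 28 lists, 2 higher and 14 lower. Without both far 2 Gy arrays it was 16 as well, but 4 of these lists were lost and 4 others gained. Those lost were NRF2 (0.181), glycolysis (0.125), unfolded protein response (0.0724) and ribosome genes (0.167). The ageing, NRF2, glycolysis and ribosome lists were also lost with the dim filter (0.0983 to 0.264) and with cyclic loess (0.0707 to 0.312), and the unfolded protein response with the dim filter (0.0511). Lists not called in any of the 7 comparisons had, in the average, an adjusted p of 0.304 for the Bcl2 family and caspases, 0.362 for TGF-beta and BMP response, and 0.235 for megakaryocyte lineage. It was 0.0792 for lymphoid progenitor, 0.168 for mature T, NK and B cell and 0.885 for endothelial and stromal.

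The comparison of CD169-DTR with WT LT-HSC without irradiation asks what differed with depletion of CD169+ macrophages alone. Mir148a was the gene with the smallest p, at 6.06 ± 0.48 log2 in CD169-DTR and 2.95 ± 0.18 in WT (SD, n = 2, adjusted p = 0.157 in limma). The WT mean lies below the 25th percentile of every array, so no size is given here either. Cdkn1a was 2.71-fold higher in CD169-DTR (1.83 to 4.03, adjusted p = 0.936). Fzd4, a Wnt receptor, had -1.09 ± 0.13 (SE), Lgals1 (galectin) 1.28 ± 0.21 and Ebi3, a cytokine subunit, 0.765 ± 0.11, all at an adjusted p of 0.936. With limma 0 probe sets passed, and 1327 had an unadjusted p under 0.05, beside the 1514.7 that chance gives on average. The count was 5 without CD169-DTR non-irradiated replicate 1, 6 without its replicate 2, 1 without WT non-irradiated replicate 2 and 1 (Mir148a) with the intensity trend, and 0 without both far 2 Gy arrays.

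Type I interferon genes rose with depletion without irradiation, 25 of 30 higher with a mean of 0.327 ± 0.41 (adjusted p = 0.000189, and adjusted p = 0.51 with an estimated correlation), and the call remained without any 1 of the 8 arrays. Oas2 (1.39), an RNA-sensing synthetase, Rtp4 (1.35) and Oasl1 (0.835) passed when adjusted over the list alone and none over all genes. Cdkn1a passed when adjusted over the p53 list alone (0.0163) and Tgfb1 (0.725) over the TGF-beta list alone (0.0477), but neither list was called. Immediate early genes fell, 17 of 20 lower with a mean of -0.251 ± 0.257 (adjusted p = 9.34e-05, and adjusted p = 0.51 with an estimated correlation), which was lost without WT non-irradiated replicate 1 (-0.122, 0.0855). Neutrophil and progenitor genes rose, 16 of 18 higher with a mean of 0.87 ± 0.9 (adjusted p = 0.000431, and adjusted p = 0.51 with an estimated correlation), which was lost without WT non-irradiated replicate 1 (0.489, 0.102) or CD169-DTR non-irradiated replicate 2 (0.582, 0.225). HSC ageing (-0.183 ± 0.397, adjusted p = 0.00377) and LT-HSC identity genes (-0.149 ± 0.263, adjusted p = 0.00425) fell and G2/M genes rose (0.187 ± 0.265, adjusted p = 0.0419), at adjusted p = 0.818, 0.717 and 0.818 with an estimated correlation. All 3 were lost without CD169-DTR non-irradiated replicate 2 (0.162, 0.224 and 0.722). The ageing list was lost also without WT non-irradiated replicate 2 (0.308), and the G2/M list also without WT non-irradiated replicate 1 (0.499) or either CD169-DTR 2 Gy array (0.0613). Where the call remained, the mean was larger without CD169-DTR non-irradiated replicate 1 for LT-HSC identity (-0.249), without WT non-irradiated replicate 1 for ageing (-0.318) and without WT non-irradiated replicate 2 for immediate early genes (-0.38). The number of called lists, 6, was 3 without WT non-irradiated replicate 1, 10 without CD169-DTR non-irradiated replicate 1, 9 without either WT 2 Gy array and 6 without both far 2 Gy arrays. The G1/S list, not called here, was called as higher with cyclic loess and with the replicate block. Cd48 had 0.685 ± 0.50 and changed sign without CD169-DTR non-irradiated replicate 2 (-0.06), Mki67 had -0.48 ± 0.28, and neither passed.

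The comparison of CD169-DTR 2 Gy with WT 2 Gy LT-HSC asks what differed with depletion among irradiated mice. Cxcr4 was the gene with the smallest p, at 13.84 ± 0.06 log2 in CD169-DTR and 12.47 ± 0.06 in WT (SD, n = 2), 2.58-fold higher (95% interval 2.11 to 3.14, adjusted p = 0.412 in limma). Itga5, the fibronectin receptor, had 0.70 ± 0.13 (SE) and an adjusted p of 0.551. Both Cxcr4 and Itga5 passed when adjusted over the niche list alone (0.000327 and 0.0162), while the list was not called (adjusted p = 0.266). Gas6 had -0.94 ± 0.17 and the interferon-inducible gene Ifi209 -1.13 ± 0.20. Cdkn1a had the same mean of 13.24 in both groups. With limma 0 probe sets passed and 2293 had an unadjusted p under 0.05. The count was 11 without WT 2 Gy replicate 2, 3 without WT 2 Gy replicate 1, 4 without CD169-DTR 2 Gy replicate 2, 1 without either CD169-DTR non-irradiated array, 1 with all probe sets and 2, both immunoglobulin genes, without both far 2 Gy arrays.

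Cell cycle genes rose with depletion among irradiated mice. G1/S and DNA replication genes were higher in 23 of 26 with a mean of 0.338 ± 0.285 (adjusted p = 2.34e-06, and adjusted p = 0.502 with an estimated correlation). That call remained without any 1 of the 8 arrays, at 0.194 without WT 2 Gy replicate 1, but was lost without both far 2 Gy arrays (0.0846, adjusted p = 0.167). G2/M and mitosis genes were higher in 22 of 27 with a mean of 0.346 ± 0.431 (adjusted p = 1.11e-05, and adjusted p = 0.502 with an estimated correlation), which was lost without WT 2 Gy replicate 1 (0.0298, 0.387). Mki67 had -0.415 ± 0.28 and did not pass. Oxidative phosphorylation genes rose, 24 of 26 higher with a mean of 0.19 ± 0.152 (adjusted p = 2.73e-05, and adjusted p = 0.502 with an estimated correlation), and kept the call without any 1 of the 8 arrays. Repair genes rose (0.293 ± 0.436, adjusted p = 0.00315, and adjusted p = 0.502 with an estimated correlation). That call was lost without WT 2 Gy replicate 1, where the mean was 0.0848. Ribosome biogenesis genes rose (0.202 ± 0.257, adjusted p = 0.03, and adjusted p = 0.7 with an estimated correlation). Their call was lost without WT 2 Gy replicate 1, where the mean was 0.083, or without CD169-DTR 2 Gy replicate 2. Neutrophil and progenitor genes fell, 15 of 18 lower with a mean of -0.687 ± 0.805 (adjusted p = 0.00588, and adjusted p = 0.502 with an estimated correlation), which was lost without WT 2 Gy replicate 2 (0.297) or CD169-DTR 2 Gy replicate 2 (0.108). Monocyte and macrophage genes fell, 20 of 22 lower with a mean of -0.225 ± 0.276 (adjusted p = 0.00588, and adjusted p = 0.502 with an estimated correlation), which was lost without WT 2 Gy replicate 1 (0.0536) or CD169-DTR 2 Gy replicate 2 (0.0687). Siglec1 itself did not pass. Without WT 2 Gy replicate 2 the means were larger for G2/M (0.663), repair (0.501) and ribosome genes (0.32). The number of called lists, 7, was 4 without WT 2 Gy replicate 1 or CD169-DTR 2 Gy replicate 2, and 6 without both far 2 Gy arrays, where ribosome biogenesis genes had -0.0114. There 2 lists remained, oxidative phosphorylation and neutrophil genes, and 4 others were gained. The ribosome list was lost with the dim filter (0.099) and cyclic loess (0.218) too.

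**Figure D3:**
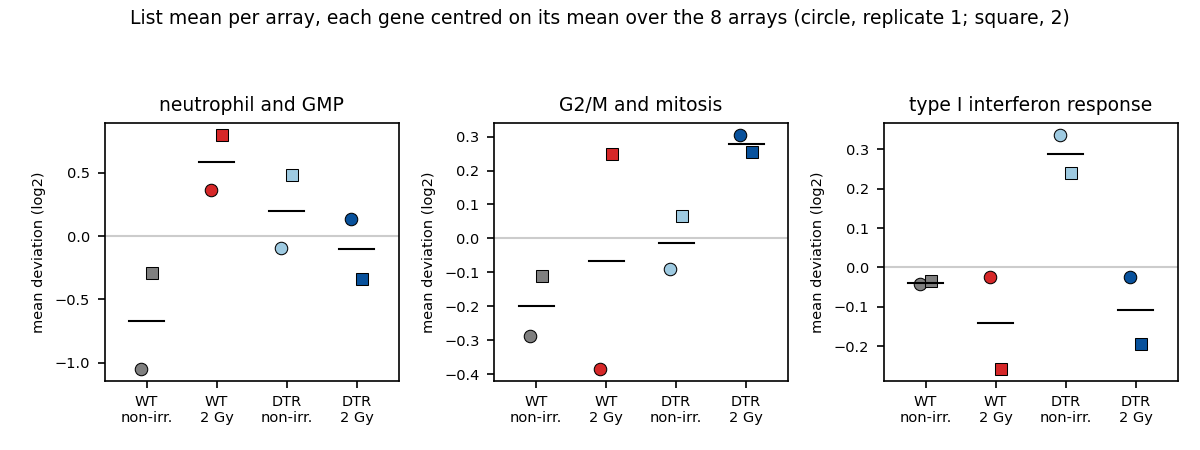
Mean over the members (log2, y axis), each gene centred on its mean over the 8 arrays, of the neutrophil and granulocyte-monocyte progenitor (GMP), G2/M and type I interferon lists in each array by group (x axis), with circles for replicate 1, squares for replicate 2 and lines for group means. The G2/M genes lie at -0.384 in WT 2 Gy replicate 1 and at 0.249 in its partner.

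The average of the depletion effects gives both doses the same weight, so a difference at 1 dose alone can also appear in it. No gene passed. Ebi3 had 0.697 ± 0.08 log2 (SE), Itga5 0.642 ± 0.09, Cxcr4 0.66 ± 0.08, Fzd4 -0.735 ± 0.10 and Oas2 1.145 ± 0.20, all at an adjusted p of 0.683 in limma with n = 4 against 4. For Cxcr4 this came from the irradiated mice, with means of 13.835 in CD169-DTR and 12.470 in WT, against 14.085 and 14.130 without irradiation. The smallest adjusted p was 0.184, in the predicted gene Gm23301, named after its values were seen. With limma 0 probe sets passed and 1919 had an unadjusted p under 0.05. The count was 4 without CD169-DTR 2 Gy replicate 2, 3 without CD169-DTR non-irradiated replicate 1 or WT 2 Gy replicate 2, 2 without WT 2 Gy replicate 1 and 0 without both far 2 Gy arrays. The depletion effects at both doses had a Pearson r of 0.0188 across probe sets and a Spearman rho of 0.052, with the same sign in 50.4%. The r was -0.0136 without CD169-DTR non-irradiated replicate 2, and 0.0471 without its replicate 1. It was 0.00328 without CD169-DTR 2 Gy replicate 2, 0.0115 without WT non-irradiated replicate 2 and -0.000403 without both far 2 Gy arrays. At an unadjusted p under 0.01 the doses shared 34 probe sets of 298 and 487, 17 in the same direction.

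G1/S genes rose in this average, 24 of 26 higher with a mean of 0.263 ± 0.182 (adjusted p = 1.6e-06, and adjusted p = 0.667 with an estimated correlation). Oxidative phosphorylation genes rose, 24 of 26 higher with 0.145 ± 0.111 (adjusted p = 1.36e-05), and immediate early genes fell, 18 of 20 lower with -0.229 ± 0.254 (adjusted p = 0.000119). Both of these had an adjusted p = 0.667 with an estimated correlation. The 3 calls remained without any 1 of the 8 arrays and without both far 2 Gy arrays. The means were 0.136 for G1/S without the far arrays and 0.0959 for oxidative phosphorylation without CD169-DTR non-irradiated replicate 2. G2/M genes rose (0.267 ± 0.305, adjusted p = 6.75e-06), a call lost without WT 2 Gy replicate 1, where the mean was 0.108. A further 6 lists were called, and as for G2/M their adjusted p was 0.667 with an estimated correlation. Ribosome biogenesis (0.176 ± 0.157, adjusted p = 0.00439), type I interferon (0.179 ± 0.309, adjusted p = 0.00976, with Oas2 past the threshold when adjusted over the list alone) and repair genes (0.158 ± 0.271, adjusted p = 0.0249) rose. LT-HSC identity (-0.157 ± 0.228, adjusted p = 0.00439), HSC ageing (-0.143 ± 0.199, adjusted p = 0.0192) and monocyte genes (-0.105 ± 0.159, adjusted p = 0.0224) fell. Without WT 2 Gy replicate 1, the ribosome (0.224), repair (0.556), identity (0.0808), ageing (0.293) and monocyte (0.0855) lists were lost, and without CD169-DTR non-irradiated replicate 2 the same 5 (0.582, 0.542, 0.0622, 0.14 and 0.155). Without CD169-DTR 2 Gy replicate 2, the ribosome (0.0819), identity (0.171), ageing (0.394) and monocyte (0.103) lists were lost. The interferon list was lost without WT 2 Gy replicate 2 (0.158) or CD169-DTR 2 Gy replicate 1 (0.263), the ageing list without WT non-irradiated replicate 2 (0.272), and the repair list without WT non-irradiated replicate 1 (0.0991) or CD169-DTR 2 Gy replicate 1 (0.21). Without WT 2 Gy replicate 2 the mean was larger for G2/M (0.425), repair (0.262) and ageing (-0.231), as it was without CD169-DTR 2 Gy replicate 1 for ageing (-0.234) and without CD169-DTR non-irradiated replicate 1 for ribosome genes (0.287). The number of called lists, 10, was 4 without WT 2 Gy replicate 1, 6 without CD169-DTR non-irradiated replicate 2, CD169-DTR 2 Gy replicate 2 or both far 2 Gy arrays, and the ageing list had 0.036 without the last, where 5 lists were lost and 1 other gained. The repair and monocyte lists were lost with the dim filter (0.0531 each) and cyclic loess (0.06 and 0.055).

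Because the receptor was placed at Siglec1, genes that lie near it can carry other alleles in CD169-DTR mice. Of the 201 probe sets of the 100 genes on either side of Siglec1, 3 (1.49%) had an unadjusted p under 0.01 in the averaged depletion effect. These were Plcb4 (-0.455), Kcnip3 (-0.79) and Bub1 (0.92). Siglec1 itself was left out. Among the other 30092 probe sets 413 (1.37%) did, and Fisher's exact test, two-sided, gave p = 0.758. The share was below that of the other genes with 50 genes on either side (0.99%), at an unadjusted p under 0.05 (4.48% against 6.35%). It was so too without WT non-irradiated replicate 1 or CD169-DTR 2 Gy replicate 2 (0.498%) and without either CD169-DTR non-irradiated array (0.995%), while it was 2.99% without CD169-DTR 2 Gy replicate 1.

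The interaction asks whether the response to irradiation differed with depletion. Cxcr4 was 3.16-fold lower after irradiation in WT and 1.19-fold lower in CD169-DTR, a difference of 1.41 ± 0.17 log2 (SE, 95% interval 1.01 to 1.81). Its adjusted p was 0.679 over all genes in limma and 0.0023 when adjusted over the niche list alone. Mir148a had an adjusted p of 0.679, and no size is given because 3 of its 4 group means lie below the 25th percentile of every array. Mmp2 had -1.23 ± 0.20, Gas6 -1.28 ± 0.24 and Cd86, a costimulatory molecule, -1.65 ± 0.28. Cdkn1a had -1.44 ± 0.34 (adjusted p = 0.839), with the same mean of 13.24 in both irradiated groups and 1.44 log2 more in non-irradiated CD169-DTR than in non-irradiated WT cells. None of these passed over all genes. With limma 0 probe sets passed and 1567 had an unadjusted p under 0.05. The count was 7 without WT 2 Gy replicate 2, 4 without CD169-DTR non-irradiated replicate 1, 2 without its replicate 2, 3 without CD169-DTR 2 Gy replicate 2, 1 without WT 2 Gy replicate 1 and 1 (an immunoglobulin gene) without both far 2 Gy arrays.

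Neutrophil and progenitor genes fell in the interaction, 17 of 18 lower with a mean of -1.56 ± 1.51 (adjusted p = 2.1e-05, and adjusted p = 0.395 with an estimated correlation). The list had 1.26 after irradiation in WT and -0.301 in CD169-DTR, and its call remained without any 1 of the 8 arrays and without both far 2 Gy arrays. Its mean per array, from the mean over the arrays, was -1.05 and -0.293 in WT non-irradiated and -0.0919 and 0.484 in CD169-DTR non-irradiated. It was 0.368 and 0.798 in WT 2 Gy and 0.134 and -0.343 in CD169-DTR 2 Gy. The interaction thus came in part from a difference between the genotypes that was present without irradiation. The other 8 called lists of the interaction had an adjusted p of 0.0424 to 0.0484, and adjusted p = 0.395 to 0.903 with an estimated correlation. Type I interferon genes had -0.296 ± 0.411, and the higher lists were repair (0.269 ± 0.536), G1/S (0.151 ± 0.436), G2/M (0.16 ± 0.374), NRF2 (0.148 ± 0.34), glycolysis (0.151 ± 0.255), niche receptors (0.122 ± 0.585) and mast cell, basophil and eosinophil (0.725 ± 1.92). All 8 were lost without WT non-irradiated replicate 2 (adjusted p of 0.0517 to 0.736) and without CD169-DTR non-irradiated replicate 1 (0.086 to 0.867). All but the niche list were lost without WT 2 Gy replicate 1 (0.164 to 0.799), where G2/M had -0.157. The repair, G2/M, NRF2, glycolysis, niche and mast cell lists were lost without CD169-DTR 2 Gy replicate 1 (0.0673 to 0.282), and the interferon, G1/S, G2/M, glycolysis and niche lists without CD169-DTR 2 Gy replicate 2 (0.0607 to 0.318). The niche list was also lost without WT non-irradiated replicate 1 (0.0873) or WT 2 Gy replicate 2 (0.164), and the mast cell list without WT non-irradiated replicate 1 (0.0814). Where the call remained, the mean was larger without WT 2 Gy replicate 2 for repair (0.477), G2/M (0.476) and G1/S (0.296). It was larger without WT non-irradiated replicate 1 for G2/M (0.248) and G1/S (0.282), without CD169-DTR non-irradiated replicate 2 (0.323) or CD169-DTR 2 Gy replicate 1 (0.26) for G1/S and without WT 2 Gy replicate 1 for the niche list (0.204). The number of called lists, 9, was 1 without WT non-irradiated replicate 2, 2 without CD169-DTR non-irradiated replicate 1, and 3 without WT 2 Gy replicate 1 or CD169-DTR 2 Gy replicate 1. It was 5 without both far 2 Gy arrays, where 7 lists were lost and 3 others gained. It was 2 with the dim filter or cyclic loess, where only the neutrophil and type I interferon lists remained. G1/S had -0.0204 without CD169-DTR non-irradiated replicate 1 and -0.103 without both far 2 Gy arrays.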

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

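The tests of explanations and of other splits of the arrays in this part were chosen only after the results they bear on were seen, while the list tests of the interaction and the fit over all probe sets were planned.

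The response of Cxcr4 to irradiation had a difference of 1.41 ± 0.17 log2 (SE) between genotypes, with an adjusted p of 0.679 over all probe sets in limma. Over the niche list alone it was 0.0023, which is not adjusted over the other lists or comparisons. RNA of other cells diluting that of LT-HSC in the WT 2 Gy samples would lower LT-HSC transcripts together by about the 1.66 log2 of Cxcr4, whereas the LT-HSC identity list had a median of -0.23 (SD 0.544, 28 members), which argues against it as the whole cause. The difference did not rest on a single array, since the interaction lay between 1.325 and 1.495 with each of the 8 arrays left out. Both WT 2 Gy arrays lay 1.28 log2 or more below the other 6. Cxcr4 was singled out by its small p, which with 2 arrays per group needs close replicates, so this adds no separate support. A response of Cxcr4 that depends on CD169+ macrophages may be behind the difference and stays open, since the adjusted p over all probe sets was 0.679. An untested difference between the genotypes other than the macrophages stays open too.

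Neutrophil and granulocyte-monocyte progenitor genes differed in their response between genotypes, with a mean of -1.56 ± 1.51 log2, an adjusted p of 2.1e-05 and adjusted p = 0.395 with an estimated correlation. Part of this lay in the non-irradiated mice. There the list stood at -1.05 and -0.293 log2 from its mean over the arrays in WT, and at -0.0919 and 0.484 in CD169-DTR. Mature neutrophils carried past the lineage gate could bring such transcripts, but the early granule and progenitor members, such as Elane and Ctsg, were lower as well. Their median interaction was -1.39 (mean -1.18, SD 0.594, 7 of 7 lower), beside -1.02 (mean -1.8, 10 of 11 lower) for the maturing neutrophil members. This argues only weakly against mature cells alone, since the list was flagged for being lower and was split after its values were seen. Of the 7 early members, 5 were higher and 2 lower after irradiation in WT, and all 7 were higher in CD169-DTR than in WT without irradiation. A single array is argued against, since the mean closest to 0 with 1 array left out was -1.18 and the largest adjusted p was 0.0132. A response that differs between genotypes stays open at that 0.395, and granulocyte-monocyte progenitors, which a Sca+ and CD48- gate should remove, were not tested as a source. S100a8 reached 13.31 log2 in WT 2 Gy replicate 2, and 1 of the 18 genes, Csf3r, is also in the niche list.

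Cell cycle genes were higher with depletion among irradiated mice and were called in the interaction, at an adjusted p of 0.0424 for G1/S and 0.0484 for G2/M, and adjusted p = 0.903 with an estimated correlation for both. For G2/M the mean depletion effect fell from 0.346 to 0.0298 (adjusted p = 0.387) without WT 2 Gy replicate 1 and was 0.663 without replicate 2, which is consistent with replicate 1 as the source, although either replicate (-0.384 and 0.249 from the mean over the arrays) could be the one that stands apart. For G1/S the mean was 0.338 with all arrays and 0.194 without it (adjusted p = 0.0164), which argues against that array as the whole cause, although without both far 2 Gy arrays it was 0.0846. Depletion of macrophages stays open for both lists, since the adjusted p with an estimated correlation was 0.502 for each. No other source was tested.

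Of the other lists called in the interaction, DNA double-strand break repair, type I interferon response and mast cell, basophil and eosinophil genes each had an adjusted p of 0.0424, and adjusted p = 0.824, 0.824 and 0.395 with an estimated correlation. Glycolysis and hypoxia, niche receptors and adhesion, and NRF2 and antioxidant defence each had 0.0439, and adjusted p = 0.395, 0.395 and 0.533 with an estimated correlation. Each of these 6 calls was lost without WT non-irradiated replicate 2 (adjusted p of 0.0517 to 0.209) and without CD169-DTR non-irradiated replicate 1 (0.086 to 0.491). Among the probe sets outside the comparisons, TC1300000696.mm.1, with no gene symbol, had -3.815 log2 for irradiation in WT (adjusted p = 0.0325 in limma over all probe sets), at 9.06 and 8.48 in the WT non-irradiated arrays and 5.53 or below in the other 6. TC0600003513.mm.1, with several symbols, had 4.645 for irradiation in CD169-DTR (adjusted p = 0.0175), 2.273 for the average (0.047) and 4.555 for depletion after irradiation (0.0199), at 9.39 and 9.27 in the CD169-DTR 2 Gy arrays and 5.19 or below in the other 6.

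All 35 splits of the 8 arrays into 4 against 4 were compared in a plain fit of 2 groups, which is not the model of the report. For irradiation, the real split gave the most of the 35 splits on each of 3 measures. A share of 1 of 35 is the smallest that can be reached, and it is not adjusted for the 6 measures tried. The measures were chosen after the values were seen, so chance is not excluded. The real split gave 2 genes at an adjusted p under 0.05 and the highest other 1, it gave 16 called lists and the highest other 14, and for each measure 1 of 35 splits gave as much. For probe sets at an unadjusted p under 0.01 the margin was 1, with 691 against 690 in the split that exchanges CD169-DTR non-irradiated replicate 1 with CD169-DTR 2 Gy replicate 1. For depletion, chance cannot be excluded: the real split gave 325 probe sets (highest other 691, 7 of 35) and 10 lists (highest other 16, 12 of 35), where 691 and 16 are those of the irradiation split. It gave 0 genes (highest other 2), a count that 35 of 35 splits must reach, so the genes test nothing here.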

How the results depend on the processing

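Leaving out both 2 Gy arrays farthest from the others was chosen only after the values were seen, and all other settings were planned. The results for named genes do not cover the fit without both far 2 Gy arrays, and most are for genes that were never called. Of them, 2118 kept direction and side of the threshold, 168 of these with array weights, 39 lost and 10 gained a call and 7 reversed. Of the results for called lists, 780 stayed, 354 lost the call and 6 reversed. Median centring changed no number of probe sets that passed. Array weights are equal within each group of 2, so they cannot lower the weight of a single array and show no stability. The number of probe sets that passed became, for irradiation in WT, 1 with cyclic loess, 1 with the replicate block and 0 with only the compared groups. For irradiation in CD169-DTR it became 2 with the intensity trend, 1 with the dim filter, 2 with all probe sets, 2 with cyclic loess, 4 without the far arrays and 1 with only the compared groups, and for the irradiation average 1 with the trend. For depletion it became 1 with the trend without irradiation, 1 with all probe sets and 2 without the far arrays after irradiation, and for the interaction 1 without the far arrays. At an unadjusted p under 0.05 with a fold of at least 1.5 the counts were 1002, 1085 and 588 for irradiation in WT, in CD169-DTR and averaged. They were 572, 1077 and 317 for depletion without, after and averaged over irradiation, and 1215 for the interaction, because that threshold is looser. With 1 array left out the counts, in the same order, ranged over 0 to 16, 0 to 5, 1 to 12, 0 to 6, 0 to 11, 0 to 4 and 0 to 7. Differences between replicates correlated across group pairs at -0.0877 to 0.159, above 0.1 in 1 of 6 pairs. That shows no strong shared effect of the replicate number over all probe sets, but it does not exclude a batch. In the plain fit of 2 groups, the split by replicate number called 13 lists and the depletion split 10. With the replicate number as a block the WT call was Cdkn1a and 2 of the 3 averaged calls were shared. The numbers of called lists were 0 for all 7 comparisons with an estimated correlation, and 1, 1, 2, 0, 0, 0 and 0 with fry. With the dim filter they were 6 for irradiation in WT and 2 for the interaction, with cyclic loess 2 for the interaction, and without the far arrays 6 for averaged depletion and 5 for the interaction. With 1 array left out they ranged over 11 to 18, 9 to 16, 12 to 18, 3 to 10, 4 to 10, 4 to 11 and 1 to 12. The correlation of irradiation effects ranged over 0.1 to 0.184 and that of depletion effects over -0.0136 to 0.0471. The latter had a rho of 0.052 and a reversed r of -0.0136 without CD169-DTR non-irradiated replicate 2 and -0.000403 without the far arrays. The share of genes near Siglec1 ranged over 0.498% to 2.99% with 1 array left out. It lay under that of other genes at 0.99% with 50 genes, 4.48% at an unadjusted p under 0.05, 0.498% without WT non-irradiated replicate 1 or CD169-DTR 2 Gy replicate 2 and 0.995% without either CD169-DTR non-irradiated array. Called lists reversed were G1/S in CD169-DTR irradiation (0.0356 without CD169-DTR non-irradiated replicate 1) and G2/M in the irradiation average (0.0535 without WT 2 Gy replicate 2), where in both the test changed sign and the mean did not. The others were G2/M in the interaction (-0.157 without WT 2 Gy replicate 1, -0.132 without the far arrays), ribosome biogenesis after irradiation (-0.0114) and ageing in averaged depletion (0.036), both without the far arrays. In 6 further cases the mean alone changed sign, as for type I interferon in WT (0.0155 without WT 2 Gy replicate 2). Reversed genes, none of them called, were Mdm2 (-0.23, -0.09) and Slamf1 (-0.415, -0.225) in CD169-DTR irradiation without CD169-DTR non-irradiated replicate 2 and CD169-DTR 2 Gy replicate 1. The others were Siglec1 there (0.025 without CD169-DTR non-irradiated replicate 1) and in the average (-0.008 with cyclic loess), and Cd48 in depletion without irradiation (-0.06 without CD169-DTR non-irradiated replicate 2). Over the arrays left out the highest values of these were 0.379 for G1/S, 0.37 and 0.476 for G2/M in the average and in the interaction, 0.39 for Mdm2, 0.675 for Slamf1 and 1.43 for Cd48, and the lowest of Siglec1 was -0.115. For these settings the cause was not tested, except that fewer arrays leave fewer degrees of freedom. How far signal over background limits dim genes was not measured.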

Other observations

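The lists and counts in this part were chosen only after the values were seen. Of 6 lists so tried over 7 comparisons, 22 of 42 tests passed with the preset correlation of camera and 0 with an estimated correlation, each adjusted over the 42. Sterol synthesis genes, which include Sqle, fell after irradiation averaged over genotypes, 15 of 16 lower with a median of -0.423 log2 (adjusted p = 2.06e-09 in limma, and adjusted p = 0.169 with an estimated correlation). MHC class II genes fell, 5 of 6 lower with a median of -0.483 (adjusted p = 3.63e-05, and adjusted p = 0.169 with an estimated correlation), and heat shock genes fell, 13 of 16 lower with a median of -0.16 (adjusted p = 0.000156, and adjusted p = 0.412 with an estimated correlation). The 53 histone genes had a median of 0.055 in that average and did not pass (adjusted p = 0.54, and adjusted p = 0.818 with an estimated correlation). Histone genes did pass as higher for irradiation in CD169-DTR (adjusted p = 0.012), depletion after irradiation (0.000187), averaged depletion (0.012) and the interaction (0.00216), at adjusted p = 0.562, 0.412, 0.562 and 0.527 with an estimated correlation. Heat shock genes passed as higher for depletion without irradiation (adjusted p = 0.000187) and averaged depletion (0.000348), at adjusted p = 0.412 with an estimated correlation for both. The early granule and progenitor and the maturing neutrophil lists had medians of 1.67 and 0.485 for irradiation in WT. That irradiation lowered sterol synthesis, MHC class II or heat shock genes may be kept as a hypothesis, and the test with an estimated correlation (0.169, 0.169 and 0.412) leaves it open.

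Single arrays held immunoglobulin genes at more than 4-fold the level of each of the other 7 arrays. Of 209 such genes this was so for 9 in WT 2 Gy replicate 1, 4 in WT 2 Gy replicate 2, 3 in CD169-DTR non-irradiated replicate 2 and 4 in CD169-DTR 2 Gy replicate 1, and for 0 in the other 4 arrays. Over all 29915 genes the numbers were 2 and 0 in the WT non-irradiated replicates, 18 and 6 in WT 2 Gy, 11 and 10 in CD169-DTR non-irradiated and 9 and 2 in CD169-DTR 2 Gy. Erythroid genes stood 1.09 log2 above their mean over the arrays in CD169-DTR non-irradiated replicate 2 and -0.812 from it in CD169-DTR 2 Gy replicate 2.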
